A study of Mus musculus with 2 samples.

How the data were processed

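Gene expression was measured in skeletal muscle of male CD2F1/Slc mice aged 11 weeks, on 2 one-colour arrays, 1 for a control sample (PBS injection) and 1 for a C26 sample (subcutaneous implantation of 1000000 colon 26 carcinoma cells in 100 µL of PBS, a mouse model of cancer cachexia). Per the labels, the RNA was total RNA labelled with Cy3. Whether RNA of several mice was pooled, which muscle was taken, how long after implantation and at what time of day are not given in the sources used here. Both arrays lay on 1 slide and carried the same scan time, so slide and scan did not differ between the groups.

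Per the file headers, the scans were read by Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes list Agilent Feature Extraction 9.5.1.1; the header version was taken as the one that made the files. The deposited scanner values are spot intensities on a linear scale, and per the file headers the processed signal had its background subtracted with spatial detrending, was detrended multiplicatively within the array, and had a surrogate put in place of spots too low to measure. A surrogate stood in for 31.9% of the non-control spots of the control array and 25.6% of the C26 array, which makes low signals less precise. A deposited table of 1 intensity per probe and array was set against the scanner values: it was on a linear scale and not centred, both columns had a median of 19.75, and 99.9% of its values in each column lay within 0.01 on the log2 scale of the quantile-normalized processed signal. How the authors made that table is not given in the sources used here, and it served as an alternative.

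Each array held 59305 non-control spots for 55681 probes. Spots flagged as outliers were left out (110 on the control array, 91 on the C26 array), the remaining spots of a probe were averaged on the log2 scale, and 1 probe was lost in this way. No spot was saturated. Each array's values were scaled by subtracting the 75th percentile of its log2 processed signals over non-control probes, and the log2 ratio was the C26 value minus the control value. A gene was represented by its brightest probe and counted as measured where that probe was well above background on both arrays. The accession or symbol of 31381 of the 55680 probes matched the reference gene table (GRCm38.p6, used for names alone), and the other 24299 kept the name in the file; this gave 34740 gene names, of which 19668 were measured. Probe positions are those of the files, on mm9.

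With 1 array per group the spread between animals could not be estimated, so no test was run and no p-value is given. Genes were counted by a fixed size, at least 2-fold. The error beside a gene's log2 ratio is the scanner software's own error of the processed signal carried to the log2 scale, and covers the measurement of spots alone. Its median over the measured genes was 0.20. As a check within the arrays, 273 probes printed in at least 8 usable copies had a standard deviation between copies of 0.11 on the control array and 0.10 on the C26 array, or 0.15 for a ratio of single spots. Of the 10 spike-in transcripts, 7 had a signal above 50 on both arrays, and their log2 ratios after scaling lay between 0.03 and 0.07. For a gene with no probe well above background on one array, an "at least" fold was computed from the brighter array's scaled value and the higher of the dim probe's own value and the lowest value well above background on that array.

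The 30 gene lists, including markers of other cell types, and the rule for named genes were fixed before the data were examined. Genes named are 22 chosen in advance, the 12 highest and 12 lowest log2 ratios, the 5 largest "at least" folds in each direction (all without clone or model names; names of array positions, array designs and numbered clones, which the rule did not list, were left out likewise), and the 2 highest and 2 lowest measured members of each list, from which the text takes examples; the value of 1 such list member is not reported here. A list was described by the median log2 ratio of its measured members and the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins; it was said to stand apart below the 2.5 or above the 97.5 percentile. Intervals of list medians are 95% bootstrap intervals over members from 2000 draws. These percentiles describe this pair of arrays, not the conditions.

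The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the 75th percentile over probes well above background on both arrays, loess on the mean signal with a span of 0.3, no filter or a stricter filter on dim probes, the mean over all measured probes of a gene, the deposited value table, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The procedure was tested on simulated data for this comparison, with 19649 genes and the software's errors as the noise: 45 of 50 genes set 2.5-fold apart, 50 of 50 set 4-fold apart and 50 of 50 set 8-fold apart were counted as at least 2-fold, against 4 of 50 set 1.5-fold apart and 11 of 19419 unchanged genes. A simulated list of 30 genes shifted by 0.4 on the log2 scale had a median of 0.49 at percentile 100, and 2 of 100 unshifted lists stood apart. These simulations hold no difference between animals and no genes that vary together, as members of a pathway may. Their unshifted lists were drawn at random from the same genes as the lists they were ranked against. They therefore do not show how often a real list would stand apart.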

Results

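The data are 1 array of control skeletal muscle and 1 array of skeletal muscle from the colon 26 (C26) tumour model of cancer cachexia, the wasting that accompanies some cancers. The series concerns the resistance of cachectic muscle to anabolic stimuli and its Igf1 expression under mechanical loading; the labels of these samples name no loading. There are no replicates, so every value below describes these arrays, and errors cover spot measurement alone. Of the non-control spots, 50.4% were well above background on the control array and 53.8% on the C26 array.

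Fbxo32 (atrogin-1) and Trim63 (MuRF1), muscle ubiquitin ligases, were 5.97-fold and 3.37-fold higher in the C26 array, at log2 ratios of 2.58 (error 0.06, 10 spots per array) and 1.75 (error 0.20). A second Trim63 probe gave 1.85. Of 19668 measured genes, 245 were at least 2-fold higher and 226 at least 2-fold lower in the C26 array, and 17860 lay within 1.5-fold. With normexp background correction, which adds an offset and draws dim genes toward a ratio of 1, these counts were 130 and 65. Under the other scalings the lower genes outnumbered the higher, which made up 43.0% to 48.9% of both together. Among 78 genes past 2-fold with several measured probes, the probes of 72 had the same sign and those of 38 all passed 2-fold.

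**Figure D1:**
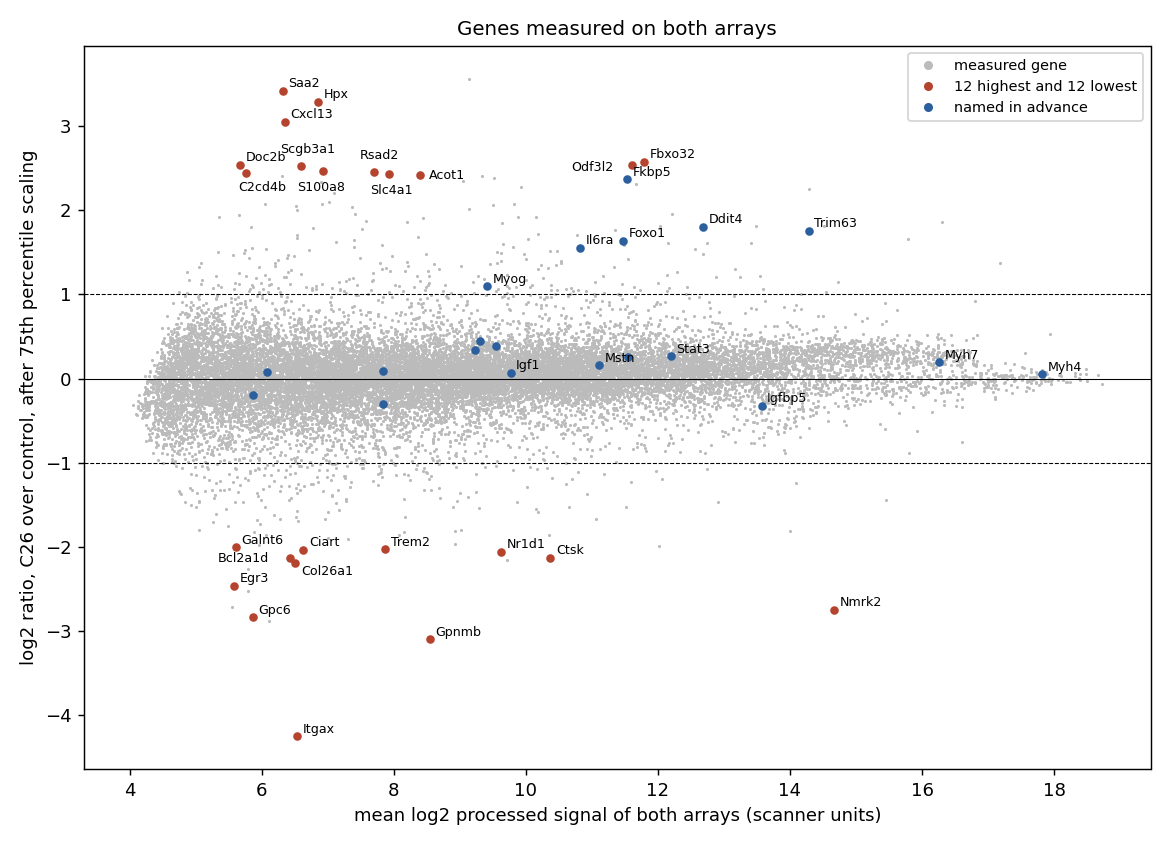
Log2 ratio of the C26 over the control array (vertical axis) against the mean log2 processed signal of both arrays (horizontal axis, scanner units), 1 point per measured gene; dashed lines mark 2-fold. Red points are the 12 highest and 12 lowest genes without clone or model names, from Saa2 at 3.42 to Itgax at -4.26, and blue points are genes named in advance.

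The 12 genes with the highest log2 ratios included transcripts of acute-phase plasma proteins, Saa2 at 3.42 (error 0.34) and Hpx (hemopexin) at 3.29 (error 0.25). Cxcl13, a B-cell chemokine, stood at 3.06 (error 0.29), S100a8, a calcium-binding protein of neutrophils, at 2.46 (error 0.24), and Rsad2, an interferon-induced antiviral gene, at 2.46 (error 0.22). Slc4a1, the anion exchanger of red cells, had a log2 ratio of 2.43 (error 0.21), and Acot1, an acyl-CoA thioesterase with near-identical paralogs, 2.42 (error 0.21). The others were Fbxo32, Odf3l2 at 2.54, Doc2b at 2.54, Scgb3a1 at 2.53 and C2cd4b at 2.45. Saa2 also has a close paralog, Saa1, whose own probe gave 0.90, so the share of each in the signal is uncertain. Several of these genes were dim on the control array, and under normexp correction Saa2 stood at 1.77, Hpx at 2.17 and Doc2b at 1.14.

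The lowest log2 ratio was that of Itgax (CD11c), an integrin of dendritic cells and some macrophages, at -4.26 (error 0.31). Further myeloid and lysosomal genes followed, with Gpnmb at -3.10 (error 0.21), the cysteine protease Ctsk at -2.13 (error 0.20), Bcl2a1d at -2.14 (error 0.23) and Trem2, a receptor of phagocytes, at -2.03 (error 0.21). Nmrk2, a nicotinamide riboside kinase of muscle, was bright on both arrays and stood at -2.75 (error 0.20), 6.74-fold lower in the C26 array. The clock genes Nr1d1 and Ciart stood at -2.06 (error 0.20) and -2.03 (error 0.22). Egr3, an immediate early gene, had -2.47, the matrix genes Gpc6 and Col26a1 -2.84 and -2.19, and Galnt6 -2.01. A second Col26a1 probe gave -1.15, and under normexp correction Itgax stood at -2.42, Gpc6 at -1.31, Egr3 at -1.01 and Galnt6, at -0.94, was no longer 2-fold lower.

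Another 1440 genes were well above background on the C26 array alone and 356 on the control array alone; the lowest signal well above background was 18.5 on the control array and 14.1 on the C26 array. Of these genes, 102 were at least 2-fold higher and 161 at least 2-fold lower in C26 by their bounds. The largest bounds were at least 7.62-fold higher in C26 for Rap2c, 6.82-fold for Vmn1r34, 6.25-fold for Itih3, 6.20-fold for Ahsp, a chaperone of alpha globin, and 5.54-fold for Efcab7. In the other direction, Ptpn7, a phosphatase of haematopoietic cells, was at least 12.3-fold lower in C26, Olfr255 at least 11.9-fold, Slc17a2 at least 10.3-fold, Syna at least 8.82-fold and Slc24a5 at least 8.67-fold. Each of these rests on 1 spot per probe.

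Igf1, the growth factor named in the series title, gave different ratios with different probes. Its brightest probe (chromosome 10, 87378456 to 87378515, mm9, listed under transcript variant 2) had a log2 ratio of 0.07 (error 0.14), which is the value fixed in advance as the result. The other 4 probes, listed under transcript variant 1, gave -0.29 and -0.23 from overlapping positions at 87393561 to 87393620 and 87393581 to 87393640, -0.00019 at 87395924 to 87395983 and -0.84 at 87399581 to 87399640, each with an error of 0.14 to 0.15. The last is 1.79-fold lower in the C26 array. The mean over the 5 probes was -0.26 with a standard deviation between probes of 0.36, so the sign of the Igf1 value depended on how probes were combined.

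**Figure D2:**
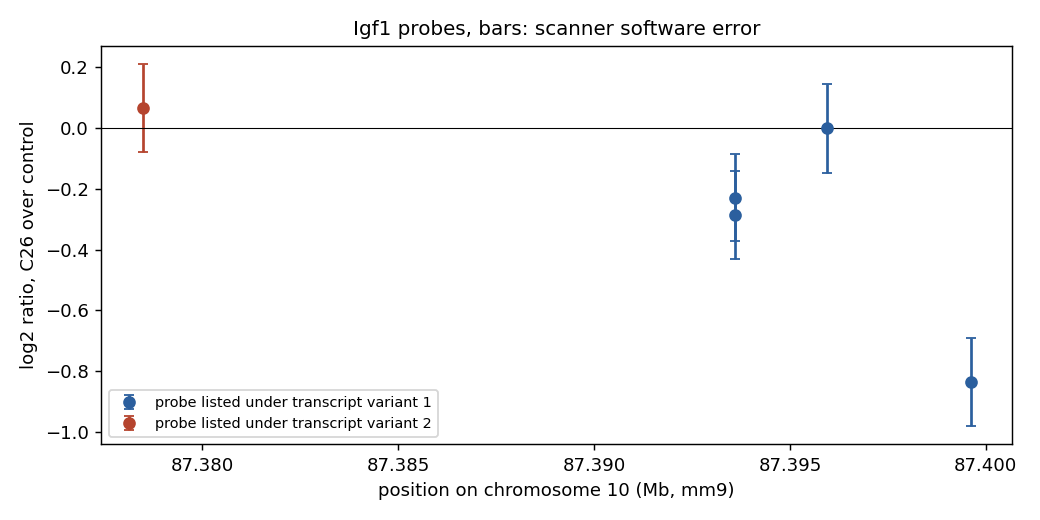
Log2 ratio of the C26 over the control array for each of the 5 Igf1 probes (vertical axis) against position on chromosome 10 in Mb of mm9 (horizontal axis); bars are the scanner software's error and colours the transcript variant given in the file. The probe under variant 2 lies at 0.07 and the probes under variant 1 between -0.84 and 0.

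Of the 29 measured genes of IGF and insulin signalling, none was 2-fold different, and the list median of 0.07 lay at percentile 53.4 of random lists. Irs1, an adaptor of the insulin and IGF1 receptors, had a log2 ratio of -0.77 and Igfbp2 -0.72, whereas Gsk3b stood at 0.57 and Irs2 at 0.47. Igf1r had 0.34 (error 0.20), Igf2 0.07, and the binding proteins Igfbp3 and Igfbp5 0.09 and -0.32. In the TGF-beta, myostatin and BMP list (median 0.09, percentile 80.0, but -0.07 and percentile 2.2 with the stricter filter on dim probes), Inhbb was the 1 of 28 measured members at least 2-fold higher, at 1.15, followed by Acvr1b at 0.95, while Fstl1 stood at -0.67 and Acvr2b at -0.49. Mstn (myostatin), a negative regulator of muscle mass, had 0.16 (error 0.20).

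Targets of FoxO factors and glucocorticoids stood highest among the lists of signalling pathways. Their median log2 ratio was 1.21 over 28 measured members (interval 0.52 to 1.31, percentile 100), and 15 were at least 2-fold higher and none 2-fold lower in the C26 array. Fkbp5, a chaperone induced by glucocorticoids, had 2.37 (error 0.20), Pdk4, which restrains pyruvate oxidation, 2.26, Ddit4, an inhibitor of mTORC1, 1.81 and Foxo1 itself 1.64. Klf15 stood at 0.45, and the list's lowest members were Mt3 at -0.09 and Bcat2 at 0.02. Foxo3 was not well above background on the control array and was at least 2.05-fold higher in C26.

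**Figure D3:**
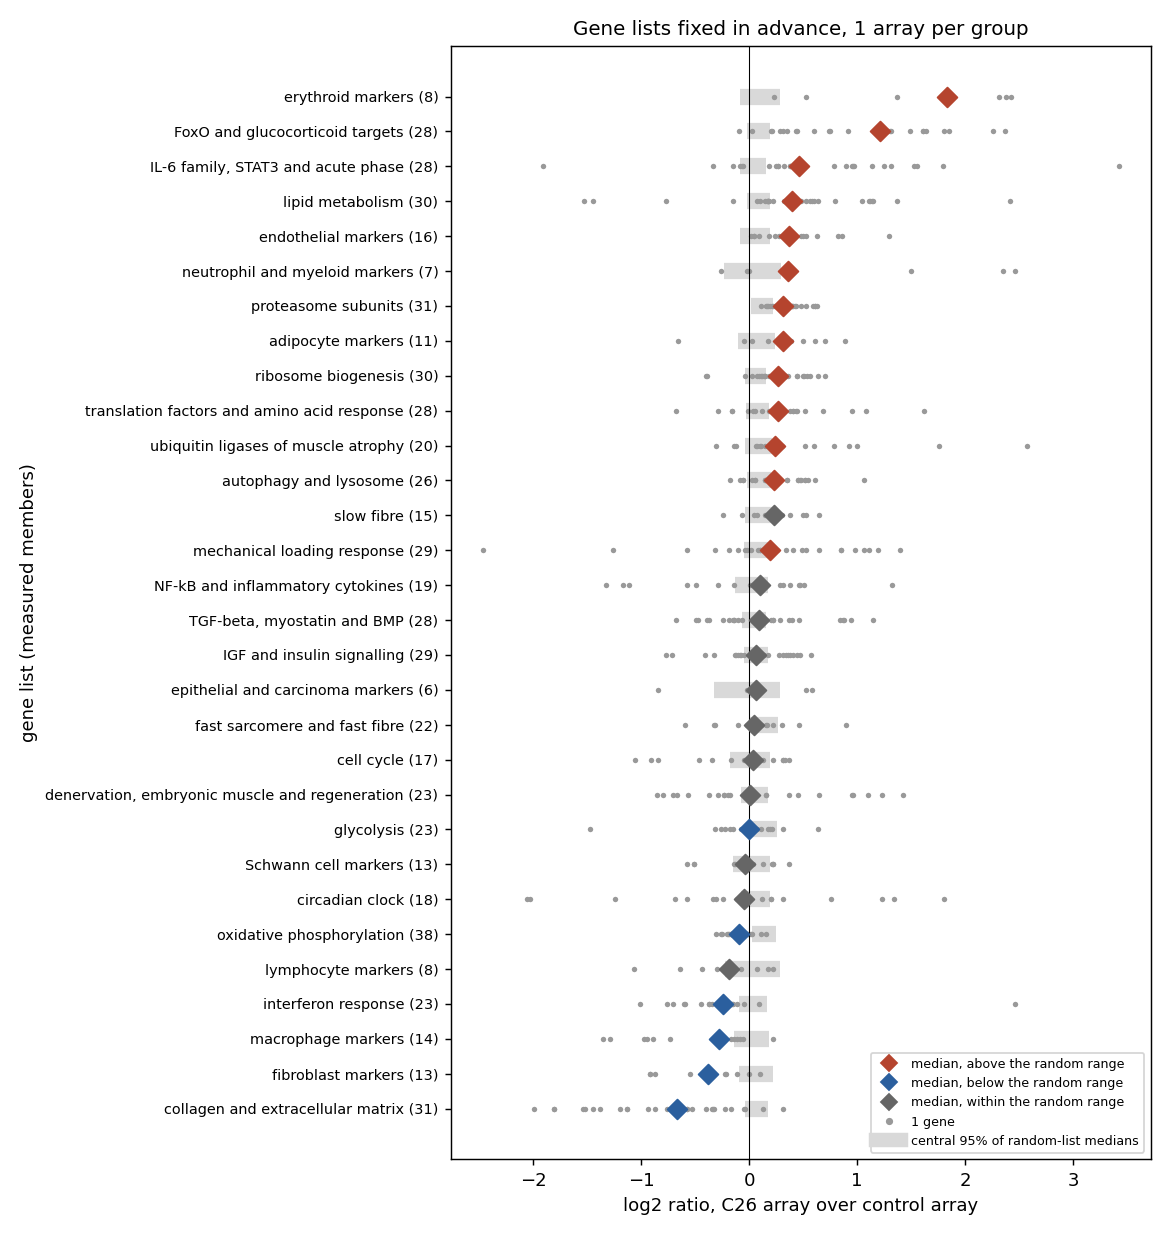
Log2 ratio of the C26 over the control array (horizontal axis) for each measured member (small points) and the median (diamonds) of the 30 gene lists (vertical axis, number measured in parentheses); grey bars hold the central 95% of medians of 10000 matched random lists. Medians run from 1.83 for erythroid markers to -0.67 for collagen and extracellular matrix.

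The ubiquitin ligase list had a median of 0.24 over 20 genes (percentile 99.3) with 3 at least 2-fold higher, and its lowest members were Fbxo30 at -0.31 and Fbxo40 at -0.14; under normexp correction its percentile was 97.4. All 31 proteasome subunits measured had ratios above 0, with a median of 0.32 (interval 0.26 to 0.39, percentile 100). The median lay below that interval with quantile normalization, loess and the deposited value table, where all 31 stayed above 0. None was 2-fold higher, and Psmd2 and Psmd4 led at 0.63 and 0.61 while Psmd14 had 0.11 and Psma1 0.16. Autophagy and lysosome genes had a median of 0.23 (percentile 99.3) with 1 of 26 at least 2-fold higher, Depp1 at 1.07, followed by the cargo receptor Sqstm1 at 0.61; Ctsb had -0.18 and Atg5 -0.08. With the mean over all probes of a gene this list's percentile was 92.7. Ribosome biogenesis genes had a median of 0.27 over 30 members (percentile 99.99), from Wdr43 at 0.70 and Nop14 at 0.63 to Pes1 at -0.40 and Taf1b at -0.39. Translation factors and genes of the amino acid response had a median of 0.27 over 28 (percentile 99.98), with Chac1 and Asns at least 2-fold higher at 1.61 and 1.08 and Slc7a5, an amino acid transporter, at -0.68 and Ddit3 at -0.29. That median was lower with quantile normalization, loess and the deposited value table, where the list still stood apart. Second probes had the other sign for Slc7a5, Pes1 and Fbxo40, at 0.38, 0.28 and 0.18.

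The IL-6, STAT3 and acute-phase list had a median of 0.46 over 28 members (percentile 100), with 7 at least 2-fold higher and Timp1, a metalloproteinase inhibitor, lower at -1.91. Besides Saa2, the fibrinogen chain Fgb stood at 1.80 and the receptor Il6ra at 1.56 (error 0.20), while Stat3 had 0.26, Socs3 0.38 and Lifr -0.33. Another Lifr probe gave 0.31. NF-kB and cytokine genes did not stand apart (median 0.10, percentile 84.1), though with the stricter filter on dim probes they did, as higher (median 0.29, percentile 98.2): Tnfrsf12a, the TWEAK receptor, had 1.32 and Nfkbia 0.51, and the chemokines Ccl7 and Ccl2 had -1.33 and -1.17. The interferon list was lower in the C26 array, with a median of -0.24 and 21 of 23 members below 0, among them Gbp3 at -1.02 and Iigp1 at -0.76; Rsad2 and Isg15, at 2.46 and 0.09, were the exceptions. The mechanical loading list had a median of 0.19 over 29 genes (percentile 98.4), with 4 at least 2-fold higher, led by Ccn1 at 1.39 and Myc at 1.19, and 2 lower, Egr3 at -2.47 and Postn at -1.26. With no filter on dim probes its percentile was 95.1.

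Collagen and extracellular matrix genes were lower in the C26 array, with a median of -0.67 over 31 members (interval -0.93 to -0.53, percentile 0). Of these, 10 were at least 2-fold lower and none 2-fold higher; Col3a1 and Col1a1 stood at -1.996 (error 0.20) and -1.81 (error 0.20), and the highest members were Eln at 0.31 and Timp3 at 0.12. Fibroblast markers had a median of -0.38 over 13 (percentile 0), with Cd248 and Dpt at -0.92 each, Medag at -0.01 and Dpep1 at 0.10. Macrophage markers had a median of -0.28 over 14 (percentile 0.07), 2 of them at least 2-fold lower, Cd68 at -1.35 and Ms4a7 at -1.29, against Mertk at 0.22 and C1qc at -0.05.

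Erythroid markers had the highest median of all lists, 1.83 over 8 measured members (interval 0.52 to 2.38, percentile 100), and 6 were at least 2-fold higher. Slc4a1 stood at 2.43, while Bpgm had 0.23 and Hba-a2 0.52; globin genes have near-identical copies whose probes may not tell them apart. Neutrophil and myeloid markers had a median of 0.36 over 7 (percentile 99.3), with S100a8 and S100a9 at 2.46 and 2.35 and Csf3r and Camp at -0.26 and -0.02; with no filter on dim probes the percentile was 93.9. All 16 endothelial markers had ratios above 0 (median 0.37, percentile 99.99), or 13 to 14 of them under the other scalings, led by the tight junction gene Cldn5 at 1.30 and Vwf at 0.86, with Kdr at 0.01 and Emcn at 0.04. The mean over the probes of Kdr was -0.31. Adipocyte markers had a median of 0.31 over 11 (percentile 99.7), with Cidea at 0.88 and Adig at 0.70 and Lep (leptin) and Plin1 at -0.66 and -0.04. Lymphocyte markers (median -0.19 over 8, percentile 4.2), Schwann cell markers (-0.04 over 13, percentile 22.3) and epithelial and carcinoma markers (0.06 over 6, percentile 69.4) did not stand apart. With no filter on dim probes the lymphocyte list did, as lower (median -0.30, percentile 1.3), and with the stricter filter its median was 0.07. Gzma was the lowest lymphocyte marker at -1.07 and Cd79b had -0.64, against Cd4 at 0.22 and Cd79a at 0.18. S100b and Egr2 had -0.52 and -0.58 among Schwann cell markers, with Mbp at 0.36 and Ncmap at 0.22, and among epithelial markers Krt19 had -0.84 and Cdh1 -0.02, with Lgals4 at 0.58 and Cldn7 at 0.53.

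Genes of the contractile apparatus differed little. The fast fibre list had a median of 0.04 over 22 members (percentile 13.3), which was below 0 under median scaling, loess and the 75th percentile over probes above background, and none was 2-fold different; Mylk2 and Actn2 had 0.90 and 0.46, and Casq1 and Mylpf -0.60 and -0.32. A second Actn2 probe gave -0.16. Myh4, the fast IIb myosin, had 0.05 (error 0.20), a sign that turned under loess and the 75th percentile over probes above background, and Myh7, the slow myosin, 0.19 (error 0.20). The slow fibre list had a median of 0.23 over 15 (percentile 94.7, but 98.6 with the stricter filter and 98.4 with unmatched random lists), with Csrp3 at 0.64 and Myoz2 at 0.53 and Pln and Casq2 at -0.25 and -0.07. Genes of denervation, embryonic muscle and regeneration had a median of 0.0067 over 23 (percentile 24.6), a sign that turned under every other scaling; Myod1, Gadd45a and Myog, at 1.42, 1.23 and 1.099 (error 0.06), were at least 2-fold higher, and Actc1 and Cd34 had -0.85 and -0.80. The median of this list was the value of Myh8, whose probe was brighter than that of Myh4 on both arrays. Whether the Myh8 probe tells myosins apart was not tested. Pax7, of satellite cells, had -0.20 (error 0.25). The cell cycle list had a median of 0.04 over 17 (percentile 60.7), below 0 under median scaling and the 75th percentile over probes above background, with Aurka at -1.05 and Ccnd1 at -0.91 and Mcm3 and Tyms at 0.37 and 0.33.

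Lipid metabolism genes had a median of 0.40 over 30 members (percentile 100), with 7 at least 2-fold higher and 2 lower. Acot1 and Acot2 led at 2.42 and 1.37, and the lipogenic genes Scd1 and Fasn had -1.53 and -1.44. Adipocyte markers were higher as well, at the median of 0.31 given above, and how far fat cells contribute to the lipid list was not tested. Oxidative phosphorylation genes had a median of -0.09 over 38 (percentile 0), none 2-fold different, and of -0.24 with quantile normalization and -0.22 with loess; members ran from Cyc1 and Cox7a1 at -0.31 and -0.26 to Ndufa2 and Cox6a2 at 0.16 and 0.11; Ppargc1a, a regulator of mitochondrial genes, had 0.26 (error 0.20). The glycolysis list had a median of 6.2e-05 over 23 (percentile 2.4), a position kept in 0 of the 8 alternatives that can move a percentile, with a median below 0 under every other scaling; Pfkfb3 was 2-fold lower at -1.47, Eno1 had -0.31, and Fbp2 and Ugp2 0.64 and 0.31. Among 18 measured clock genes, 3 were at least 2-fold higher and 3 at least 2-fold lower, and the median of -0.05 (percentile 5.7) did not stand apart. It did, as lower, with no filter on dim probes (percentile 0.75) and with the mean over all probes (percentile 0.54), and the median was 0.12 with the stricter filter. Nfil3 and Arntl had 1.81 and 1.34, against -2.06 for Nr1d1, -2.03 for Ciart and -1.24 for Dbp; the labels do not give the hour at which the muscles were taken.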

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

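The alternatives that counted only names matched to the reference table, or left out the erythroid, matrix, macrophage and added lists, were chosen after seeing the data. The main counts of genes at least 2-fold higher and lower in the C26 array were 245 and 226. They were 130 and 65 with normexp correction, 1579 and 1316 with no filter on dim probes, 109 and 60 with the stricter filter, 859 and 949 at 1.5-fold and 68 and 45 at 3-fold. The last 2 follow from the threshold. The filters change how many genes count as measured, 34740 with none and 11059 with the stricter one against 19668. All genes past 2-fold with the stricter filter were past it in the main setting. How far the offset of normexp accounts for its counts was not tested. Across the other scalings the counts were within 1.5 times, and the share of higher genes, 52.0% in the main setting, lay between 43.0% and 48.9%. With matched names alone the counts were 194 and 179, and without the named lists 225 and 211. The Igf1 log2 ratio was -0.26 with the mean of its probes, and the mean was -0.11 without the lowest probe; it lay between 0.01 and 0.07 otherwise. Of 268 list medians under the alternatives, 245 lay within the main interval. Quantile normalization and the deposited value table gave nearly the same values, so wherever alternatives are counted they are not separate checks. The proteasome median was 0.19 with quantile normalization and with the value table, 0.26 with the 75th percentile over probes above background and 0.20 with loess. Under quantile normalization, loess and the value table the translation median was 0.17, 0.18 and 0.17 and the slow fibre median 0.13, 0.12 and 0.13. The fast fibre median was -0.016 with the 75th percentile over probes above background and -0.082 with loess. The oxidative phosphorylation median was -0.24 with quantile normalization and the value table, -0.14 with median scaling, -0.15 with the 75th percentile over probes above background and -0.22 with loess. The glycolysis median turned sign, at -0.010 with normexp, -0.082 with quantile normalization and the value table, -0.044 with median scaling, -0.059 with the 75th percentile over probes above background and -0.10 with loess. Median scaling and the 75th percentile over probes above background moved the list medians by shifting all genes alike. For the other alternatives the cause was not tested. Of the 30 lists, 20 kept their side of the percentile bounds in each of the 8 alternatives that can move a percentile, where it gave a value; the other 2, median scaling and the 75th percentile over probes above background, shift all genes alike and leave percentiles as they are. Of 1311 values of 152 named genes measured on both arrays, 1280 stayed within the 95% range that their error gives, and none of a gene past 2-fold changed sign. Many of these could not leave it. The filters do not alter the value of a gene they keep, nor does the mean for a gene with 1 measured probe. Median scaling and the 75th percentile over probes above background shift all genes by less than that range. Values left the range for 27 of 152 genes with normexp and 4 of 152 with the mean of all probes. With normexp 13 genes dropped below 2-fold, Myog, Galnt6, Depp1, Ccl2, Ccl7, Gbp3, Inhbb, Myc, Postn, Asns, Fasn, Ms4a7 and Gzma, and with the mean of all probes Pfkfb3 did. The "at least" folds were not recomputed under the alternatives. Leaving out a replicate, or taking slide or scan as a block, was not possible with 1 array per group. No paired analysis was possible because each group has 1 array. Signal over background limits the dim genes most, where the software's error and the choice of background correction weigh heaviest.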

Other observations

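The tests on single-copy erythroid genes, lymphocyte markers, the evenness of erythroid members, regenerating fibres and the difference between collagen and fibroblast medians were chosen after the results they bear on had been seen, as were all 5 added gene lists; the bounds for liver transcripts and repair macrophages were written before their values were seen. A bound counted as passed only where the whole 95% bootstrap interval over list members lay beyond it. That requirement was added after the bounds were written, and by the medians alone 4 of the 6 tests would have passed the bound against their explanation. It left 3 of these 4 open. The lymphocyte test met it as well, and was left open by a further condition, that most of the list be measured, which was set after its values had been seen.

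Transcripts of plasma proteins made mainly by the liver were among the higher genes of the C26 array. In an added list of 18 acute-phase transcripts, 11 of them also in the fixed lists, 15 were measured with a median of 0.90, and 7 were at least 2-fold higher, among them Hpx at 3.29 and Itih4 at 2.21. Fgb and Fgg stood at 1.80 and 1.53, whereas the third fibrinogen chain, Fga, had -0.07. In an added list of 25 abundant liver transcripts outside the acute phase, 19 were measured on both arrays, so the control muscle sample gave signal for them too. Of these, 5 were at least 2-fold higher, including Ahsg at 1.46, Ambp at 1.43 and Cyp2e1 at 1.27, while Apoa2, Apoc3 and Apoh had 0.06, 0.01 and 0.10.

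Liver RNA in the C26 sample could account for the plasma protein transcripts, and would raise abundant liver transcripts outside the acute phase alike. Their median log2 ratio was 0.090 (interval -0.10 to 0.98), below the bound of 0.5 set against this explanation, but the interval reached past it, as it did with Apoa1 put at its bound (median 0.093, interval -0.046 to 1.00). The members went both ways, with 5 at least 2-fold higher but Vtn, Mup3 and Fabp1 at -0.45, -0.39 and -0.32. Cps1, Hpd and Tdo2 were well above background on neither array and do not enter the median. Apob was so on the C26 array alone, with a signal of 19.3 there and 20.4 on the control array. Measured members that were lower argue against a rise of all liver transcripts alike, whereas the higher ones go with it. The median did not decide between them, so liver RNA stays open. Expression in muscle under the tumour is the explanation the design names, and it was not tested.

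Erythroid transcripts were higher in the C26 array, and 2 technical explanations were weighed. Shared globin probes might carry the list, but single-copy erythroid genes had a median of 2.31 over 5 measured members (interval -0.48 to 2.43, with Ermap and Tspo2 at -0.48 and 0.46), and Alas2 and Slc4a1, at 2.31 and 2.43, are not globins. More blood of the same make-up would bring lymphocyte transcripts, whose median was -0.19 with an interval of -0.64 to 0.18, wholly below the bound of 0.5 against this explanation, and was -0.079 with Cd8b1 put at its bound and 0.07 with the stricter filter on dim probes. It would also raise red cell transcripts alike, whereas Hba-a2 and Bpgm had 0.52 and 0.23 with no spot saturated. These are the lowest of 8 measured erythroid markers, of which 6 were at least 2-fold higher. They argue against it unless probes respond unequally or other cells of the muscle also carry Bpgm, which was not tested. Among 78 genes past 2-fold with several measured probes, the probes of 72 had the same sign and those of 38 all passed 2-fold. Over all 5117 genes with several measured probes, the median range between probes was 0.19. Since 17860 of all 19668 measured genes lay within 1.5-fold, that range does not show how alike probes respond at large ratios. On the other side, neutrophil and myeloid markers had a median of 0.36 (percentile 99.3, or 93.9 with no filter on dim probes), with S100a8 and S100a9 at 2.46 and 2.35. That list is thin too, with 7 of 14 markers measured, 3 of them below 0, and an interval of -0.02 to 2.35. Of the lymphocyte markers 8 of 17 were measured, and lymphocytes resident in muscle could hide a share from blood. A larger share of blood was therefore left open beside a blood richer in red cell precursors, which was not tested.

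Matrix, fibroblast and macrophage genes were lower in the C26 array, and muscle repair in the control sample is a candidate explanation. Genes of repair macrophages in no fixed list had a median of -0.31 over 10 measured members (interval -0.72 to -0.02), between the bounds of -0.5 and -0.25. It was -0.45 over 13 with Atp6v0d2 and Mmp12, at least 4.95-fold and 3.78-fold lower in C26, and Cd5l, at least 1.00-fold higher, put at their bounds. Igf1 and Plin2 were left out because their values were known when the bounds were written. With them these medians were -0.16 over 12 and -0.18 over 15, so this explanation stays open. Fewer macrophages of any kind in the C26 sample would lower these genes too, and macrophage markers had a median of -0.28. The test therefore cannot tell repair in the control sample from such a difference. Genes of regenerating fibres, 8 of 11 in the fixed lists, had a median of -0.084 (interval -0.67 to 0.65), which leaves regeneration open. They include Myh8, whose signal of 348845 on the control array was above the 233072 of Myh4. Whether its probe tells myosins apart was not tested. A lower share of fibroblasts would lower their markers as much as collagen genes, yet the collagen median lay below the fibroblast median by a difference of -0.29 (interval -0.72 to -0.02), which argues against that share as the whole cause, although the interval ends close to 0 and the list holds Gsn and Medag, bright on both arrays. Lower matrix expression under the tumour was not tested apart from these.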
